A study of Homo sapiens with 12 samples.

How the data were processed

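RNA was measured in cultured human mesenchymal stromal cells, the plastic-adherent, spindle-shaped cells that can be grown out of many tissues. The 12 samples came from 12 different people per the series design: 6 from liver, 3 from adipose tissue and 3 from bone marrow. Per the labels' protocols, the cells grew for roughly 2 weeks before passage while an imaging incubator recorded their confluency each day. RNA was taken with TRIzol and RNeasy columns and made into TruSeq v2 libraries, per the same protocols. Passage number and confluency at harvest are not given per sample in the sources used here.

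The authors deposited 1 table of gene values in normalized CPM, treated here as signal: the gene's reads divided by a scaling factor that differs between samples. Per the submitters' processing notes, reads were aligned with TopHat2 to the human genome build hg19 and processed with edgeR. The program that counted reads, the gene annotation, the use of strand and any removal of genes with low counts are not given in the sources used here. In every sample 100% of the values were whole multiples of that sample's smallest step, within a tolerance of 0.05 reads, so whole reads could be recovered. Sums of the values ran from 849992 to 1108780 with a median of 1012426, so the library sizes had been adjusted by the authors and were not adjusted again. The table held 14741 genes. The lowest mean over the 12 samples was 0.954 CPM, and genes with little expression in all samples may be missing from it.

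The recovered reads numbered 61868286 to 103291541 per sample, with a median of 74288664. A single read corresponded to 0.00884 to 0.0170 CPM. A count of 0 allows a level up to 3 reads, or 0.0265 to 0.0511 CPM depending on the sample, and this floor covers counting error only, because duplicate reads were not marked with molecular identifiers. Between 7 and 23 of the 14724 genes used had a value of 0 in a given sample.

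Genes on the Y chromosome together with XIST and TSIX, 17 in all, were left out, because they tell the sex of a donor. Of the 14724 others, 14715 reached 1 CPM in at least 3 samples and were tested. Values were analysed as log2(CPM + 1). Linear models were fitted with limma 3.58.1 in R 4.3.3, with variance moderation that follows mean expression (limma-trend), and p values were adjusted by the Benjamini-Hochberg method over all 14715 genes; a gene was called at an adjusted p under 0.05. Liver was compared with non-liver in a fit with 2 groups. Liver with adipose, liver with bone marrow, and adipose with bone marrow were compared in a fit with 3 tissues. All 4 comparisons and their tests were fixed before the data were examined. Errors are SD over samples for CPM and SE of the fit for log2 fold changes. Samples were grouped by tissue as the labels state, and the design is not paired.

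Also fixed before the data were examined were 39 gene lists, 13 of cell type markers and 26 of pathways, families and positional transcription factors. They held 672 genes, of which 490 were in the table; 34 lists had at least 3 measured members and were tested with limma's camera, at its preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. Lists were tested for liver against non-liver and for adipose against bone marrow.

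Named genes followed a rule fixed in advance. For liver against non-liver they were the 12 with the largest rise and the 12 with the largest fall among called genes whose 6 liver and 6 non-liver samples did not overlap and whose higher group averaged at least 5 CPM; for the comparisons between tissues, 6 each way. Up to 4 members per list were added by smallest p, as were standard markers. HLA genes outside the lists, immunoglobulin and T cell receptor segments, genes often deleted in the population, and unnamed loci were passed over. A few genes that the rule names are not reported here, though all counts and list tests include them. Where 5 or fewer members of a list passed in a direction, all may be named; these, the genes that liver held between adipose and bone marrow, and the basement membrane genes were chosen after their values were seen.

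Alternatives tried were pseudocounts of 0.25 and 5, no filter or a filter at 5 CPM, size factors computed on the values, quantile normalization, robust variance moderation and sample quality weights. Others were counts modelled with edgeR 4.0.16 (quasi-likelihood) or DESeq2 1.42.0, a replicate block, each of the 12 samples left out, the 3-tissue model and an exact rank-sum test for liver against non-liver, only the samples of the tissues compared, and a minimum absolute log2 fold change of 1. Lists were also tested with an estimated correlation and with fry. For the overlap of the calls against both tissues, liver samples were also split into groups of 3 and 3. After seeing the data, fits without the 2 most deeply sequenced libraries and with the mean of the cell cycle list as a covariate were added. On the recovered reads, edgeR called 3740 genes for liver against non-liver, 3152 for liver against adipose, 3351 for liver against bone marrow and 801 for adipose against bone marrow; DESeq2 called 4552, 4151, 4143 and 1676.

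The tests were tested on simulated data, drawn from a negative binomial with the mean expression, library sizes and dispersions of these samples. With 4-fold changes planted, limma recovered 97.0% of the changed genes for liver against non-liver, 89.4% for liver against adipose, 90.9% for liver against bone marrow and 90.9% for adipose against bone marrow; at 2-fold these shares were 73.1%, 44.8%, 53.7% and 32.8%, and at 1.5-fold 28.4%, 5.97%, 5.97% and 4.48%. All recovered genes had the planted sign, and 5, 5, 6 and 1 of the unchanged genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

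A few symbols carry ambiguous reads. In build hg19 HOXC4, HOXC5 and HOXC6 share transcribed sequence, C4A has the near-identical neighbour C4B, KRT8 and KRT18 have many processed pseudogenes, and transcripts on the other strand overlap parts of some genes. For 124 genes the symbol is shared by more than 1 identifier; a HOXC4 entry was among them, and no value is given for it.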

Results

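Gene expression was measured by RNA sequencing in mesenchymal stromal cells grown from liver (n = 6), adipose tissue (n = 3) and bone marrow (n = 3), with 1 culture per person. Per the series design, the question was what sets liver-derived stromal cells apart from those of the other sources. Liver was therefore compared with the 6 non-liver samples together and with each tissue alone. Adipose was compared with bone marrow to measure how much the non-liver sources differ. The libraries held 61868286 to 103291541 reads in the table. The deepest were adipose 2 at 103291541 and bone marrow 1 at 96121503 reads, and the 6 liver libraries held 63058712 to 80652596. The 10 most abundant genes took 14.5% to 23.5% of the reads, and mitochondrial genes 0.660% to 1.02%.

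Liver and bone marrow cultures each correlated best within their own tissue, while adipose 1 stood apart from the other adipose cultures. Pearson's r over the genes of log2 values, where genes are not independent replicates, averaged 0.964 between liver samples, 0.950 between adipose samples and 0.972 between bone marrow samples. Adipose 2 and 3 correlated at 0.984, but adipose 1 only at 0.930 and 0.935 with them. The highest pair of adipose with bone marrow, adipose 3 with bone marrow 1, reached 0.937. Adipose 1 itself also correlated best with the other adipose cultures. Its highest values elsewhere were 0.919 with liver 1 and 0.912 with bone marrow 3. Liver was further from adipose (mean 0.894) and from bone marrow (0.876) than these were from each other (0.925). The first principal component held 50.9% of the variance and put the liver samples between -55.2 and -32.8, bone marrow between 50.1 and 66.3, and adipose 2 and 3 at 48.1 and 45.2. Adipose 1 lay at 10.3, between liver and the other non-liver samples. The second component, with 15.3%, held adipose at 37.1 to 45.9 and bone marrow at -32.4 to -28.0.

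**Figure D1:**
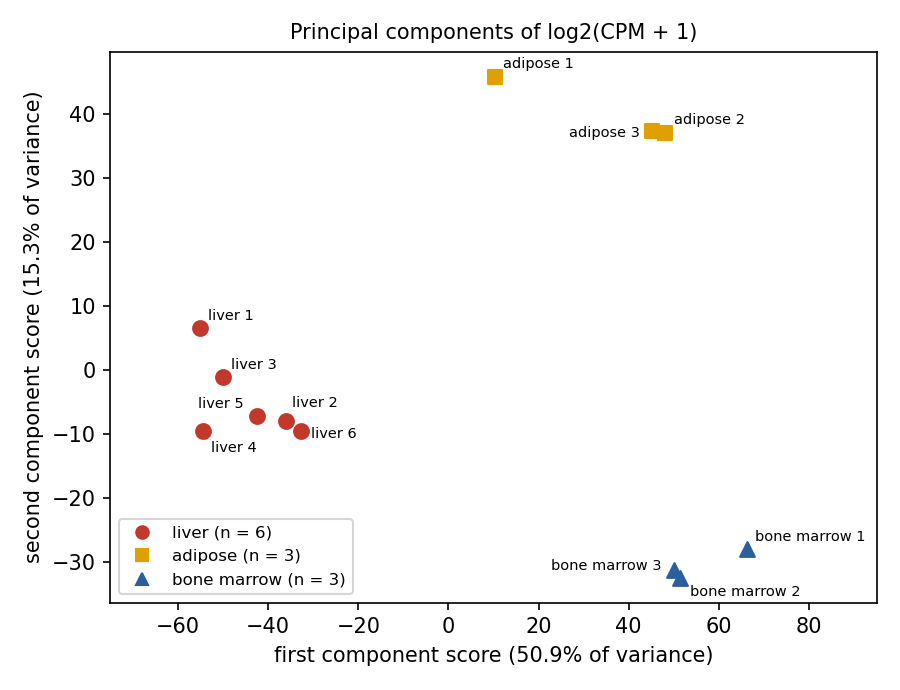
First and second principal components of log2(CPM + 1) values, 1 point per culture, coloured by tissue, with the share of variance on each axis. The liver cultures lie between -55.2 and -32.8 on the first component, and adipose 1 lies at 10.3, away from adipose 2 and 3.

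Liver-derived stromal cells were lower in measured HOX genes of paralogue groups 6 to 13 and in limb and trunk factors, with 24 called. No gene of HOX groups 12 or 13 was tested. Hepatic stellate cell markers were higher, called at 8 of 10. These lists also passed with an estimated correlation. The named gene with the largest rise, COL4A5, a chain of the type IV collagen of basement membranes (ENSG00000188153, chromosome X, 107683074 to 107940775), averaged 258 ± 55.7 CPM in liver and 2.93 ± 2.80 CPM in non-liver cells (SD, n = 6 each). Its partner COL4A6, on the same chromosome, averaged 37.3 ± 21.1 CPM against 0.186 ± 0.0405 CPM. GATA4, a transcription factor of the developing heart, septum transversum and liver mesenchyme (ENSG00000136574, chromosome 8, 11534468 to 11617511), averaged 39 ± 14.5 CPM in liver and 0.0763 ± 0.0227 CPM elsewhere. In the other direction HOXA10, a posterior homeobox factor (ENSG00000253293, chromosome 7, 27210210 to 27219880), averaged 0.210 ± 0.146 CPM in liver and 25.7 ± 3.22 CPM in non-liver cells.

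By limma, 3785 of 14715 genes (25.7%) were called between liver and non-liver cells, 1950 higher and 1835 lower in liver, of which 799 and 638 differed by at least 1 on the log2 scale. The 2 groups did not overlap at 1483 genes (10.1%), against 0.216% by chance. All 3785 called genes had the same sign against adipose and against bone marrow. The pooled fit makes this nearly certain in advance, because a large gap between these 2 tissues widens its spread. Of the 3785, 1610 were also called against both tissues. Without adipose 1 the count was 4687, and without the 2 deepest libraries it was 1949. With a replicate block it was 1191, and with the mean of the cell cycle genes as a covariate it was 618.

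The 12 named genes with the largest rise in liver came from several functions. The rule that named them required every liver sample to be above every non-liver sample. COL4A5 differed by 6.29 ± 0.37 on the log2 scale (SE, limma adjusted p = 2.96e-07), and COL4A6 by 4.87 ± 0.26 (limma adjusted p = 1.52e-07). SLC7A2, a transporter of arginine and other cationic amino acids, differed by 5.75 ± 0.41 (limma adjusted p = 1.73e-06), from 1.13 ± 1.72 to 105 ± 49.5 CPM. PDE10A, a cyclic nucleotide phosphodiesterase, differed by 5.14, GATA4 by 5.10 and IGFBP5, a secreted binding protein of insulin-like growth factors, by 5.08. IGFBP5 reached 19391 ± 4948 CPM in liver against 694 ± 502 CPM. PPP1R14A and ACTG2, which belong to the contractile machinery of smooth muscle, differed by 4.86 and 4.6, and TNNT2, a troponin of heart muscle, by 4.55. SFRP1, a secreted WNT antagonist, differed by 4.69, the methyltransferase INMT by 4.62 and BST2, an interferon-induced membrane protein that tethers viruses, by 4.55. BST2 had the smallest adjusted p of these 12 (9.39e-10, limma), from 1.78 ± 0.406 to 64.7 ± 13.5 CPM in 6 of 6 liver samples.

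The 12 largest falls were again taken only among genes with no overlap between the 6 and 6 samples. They included matrix genes and homeobox genes. COL11A1, a fibrillar collagen chain of cartilage (ENSG00000060718, chromosome 1, 103342023 to 103574052), fell by 5.64 ± 0.74 on the log2 scale (limma adjusted p = 0.000238), from 371 ± 265 CPM in non-liver to 6.71 ± 9.02 CPM in liver cells. The microfibril gene FBN2 differed by -5.51 and HAPLN1, which links hyaluronan to proteoglycans, by -5.48. HAPLN1 spread widely among the non-liver samples (361 ± 416 CPM). The adhesion protein gene TENM3 differed by -5.10 and FAM20A by -4.91. Differences of -4.6 for the scavenger receptor COLEC12, -4.55 for the matrix protein MXRA5, -4.52 for the hyaluronan synthase HAS1 and -4.43 for NDNF followed. HOXA10 differed by -4.46 ± 0.11 and HOXC10 by -4.40 ± 0.10, with the smallest limma adjusted p values among these 12 (9.91e-11 and 7.99e-11), in all 6 liver samples. With the cell cycle mean as a covariate TNNT2 (adjusted p = 0.0801) and HAPLN1 (adjusted p = 0.202) were not called by limma.

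**Figure D2:**
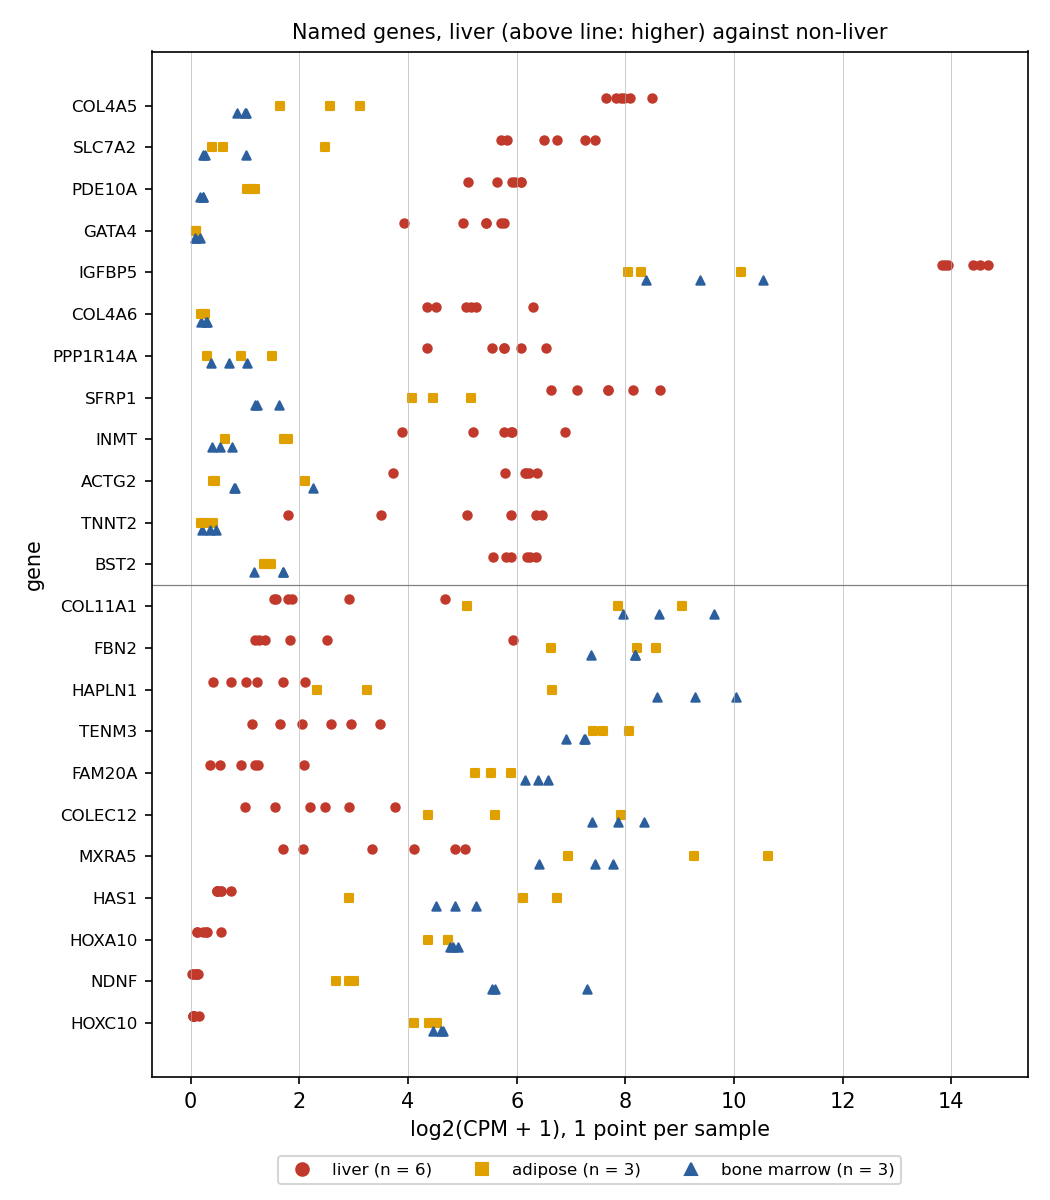
Values as log2(CPM + 1) on the horizontal axis for genes with the largest rise (above the line) and fall (below it) between liver and non-liver cultures, 1 point per culture, coloured by tissue. For each gene the 6 liver cultures lie apart from the 6 non-liver cultures, as the rule for naming them required.

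Positional transcription factors of the limbs and trunk were lower in liver as a group. Of 15 tested factors of limb and trunk mesenchyme, 13 fell in liver and none rose (14 adjusted over the list alone), with a median log2 difference of -1.98 and the list mean of all 6 liver samples below all 6 others (limma camera adjusted p = 1.76e-12, adjusted p = 0.00168 with an estimated correlation). Among those lower were EN1 (-3.68), IRX5 (-3.01), TWIST1 (-1.88) and PRRX1 (-1.90), a marker of limb and body wall mesenchyme. TBX18 and MEOX2 were not called. Of 9 HOX genes of paralogue groups 6 to 9, 8 fell (8 adjusted over the list alone), including HOXC6 (-4.06), HOXA9 (-3.88) and HOXA7 (-2.59). They gave a median of -2.59 in 6 of 6 samples (limma camera adjusted p = 3.44e-11, and adjusted p = 0.00918 with an estimated correlation). Of 12 HOX genes fixed for groups 10 to 13 only 3 were tested, none of them in groups 12 or 13. All 3 fell, namely HOXA10, HOXC10 and HOXA11 (3 adjusted over the list alone, median -4.40, 6 of 6 samples). Their limma camera adjusted p was 4.39e-07, and 0.00918 with an estimated correlation. The anterior groups 1 to 5 split. HOXB5 (1.69), HOXB4 (1.15) and HOXB3 (0.78) were higher in liver, while HOXA5 (-2.13), HOXC5 (-1.72) and HOXD3 (-2.65) were lower. In all 3 were higher and 4 lower of 9 (3 and 5 adjusted over the list alone, limma camera adjusted p = 0.0871, median -0.59).

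Factors of the splanchnic mesoderm, from which the mesenchyme of liver and gut develops, rose at 8 of 10 tested genes and fell at 1 (8 and 1 adjusted over the list alone), with a median log2 difference of 2.18 and all 6 liver list means above all 6 others (limma camera adjusted p = 7.66e-06). This list's call was lost with an estimated correlation (adjusted p = 0.158 with an estimated correlation). FOXF1 rose by 4.02, TCF21, an epicardial and stellate cell factor, by 3.53, NR2F1 by 2.08 and TBX20 by 2.02, beside GATA4, HAND2, HLX and NR2F2. FOXF2 fell by 1.54, and GATA6 differed by 0.67 without passing. Hepatic stellate cells, the vitamin A storing pericytes of the liver, have markers that rose at 8 of 10 genes with none lower (8 adjusted over the list alone; median 2.67). Every liver sample lay above every other in the list mean (limma camera adjusted p = 3.82e-06, adjusted p = 0.0305 with an estimated correlation). They included the lectins COLEC10 (4.39) and COLEC11 (2.98), the hepatocyte growth factor HGF (3.11) and the peptide receptor VIPR1 (4.52), with DES, CYGB and HAND2. Smooth muscle and pericyte genes rose at 6 of 13 (7 adjusted over the list alone; median 1.14, 6 of 6 samples, limma camera adjusted p = 0.000478), with adjusted p = 0.277 with an estimated correlation. The pericyte gene RGS5 rose by 4.01, NOTCH3 by 1.57 and MYL9 by 0.90; ACTA2 (1.33, adjusted p = 0.101) and TAGLN (0.50, adjusted p = 0.37) did not pass in limma.

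Cell cycle genes were lower in liver at all 28 list members (28 adjusted over the list alone), with a median log2 difference of -2.07. Without the 2 deepest libraries limma called 4 of the 28, with all 28 below 0 (median -1.49). All 6 liver samples had a list mean below the non-liver mean, and 4 lay below every non-liver sample (limma camera adjusted p = 3.52e-11). The members move together, with an estimated correlation of 0.928, and the call was lost with it (adjusted p = 0.582 with an estimated correlation). The replication genes RRM2, MCM4, TYMS and MCM6 differed by -3.04, -2.04, -1.60 and -1.41 (limma adjusted p of 0.00591, 0.00186, 0.00247 and 0.00147), with no overlap of the samples at MCM4 and TYMS. The mitotic genes KIF20A, CCNB1 and FOXM1 differed by -2.34, -2.17 and -1.87. The list mean was 3.14 ± 0.86 in liver and 5.20 ± 1.16 in non-liver cells (log2, SD, n = 6 each; exact two-sided permutation p = 0.0108), with adipose 1 lowest of the non-liver samples at 3.30. With this mean as a covariate, 18 of the 24 called HOX and limb and trunk genes were still called lower, against 15.6% of all called genes. The latter had smaller differences (median absolute log2 difference 0.744, against a median of -2.74 for the 24), so the shares are not alike. Lipid synthesis genes also fell, at 10 of 20 with none higher (11 adjusted over the list alone; median -0.43, 6 of 6 samples, limma camera adjusted p = 0.000334), with adjusted p = 0.277 with an estimated correlation. They included the elongase ELOVL6 (-1.50), the sterol-regulated INSIG1 (-1.73) and the fatty acid synthesis enzymes ACACA (-0.90), FASN (-0.82) and ACLY (-0.80).

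Of the genes of MHC class I antigen presentation, 4 of 17 rose and none fell (4 adjusted over the list alone; median 0.39). The list mean was above the non-liver mean in 6 of 6 liver samples (limma camera adjusted p = 0.0119), with adjusted p = 0.660 with an estimated correlation. Only 2 of these 6 lay above every non-liver sample. Adipose 2 and 3 were low at 5.34 and 5.40, while adipose 1 (6.37) and bone marrow (6.12, 6.02 and 6.40) lay near or within the liver range of 6.14 to 6.55. The 4 were TAPBP (0.80), PSME1 (0.78), ERAP1 (0.75) and PSMB10 (0.63), which load or cut peptides. Interferon-stimulated genes passed singly but not as a list by camera (10 higher and 3 lower of 28; 12 and 5 adjusted over the list alone, limma camera adjusted p = 0.0871, median 0.30, 6 of 6 samples above the non-liver mean). Beside BST2, IRF1 (1.1) and GBP1 (0.91) rose, whereas OAS3 (-1.30), IFI44 (-1.06) and USP18 (-0.76) fell. None of 7 MHC class II genes was called (limma camera adjusted p = 0.733), where the median of 0.08 and the mean of -0.25 differed in sign and the test pointed down.

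**Figure D3:**
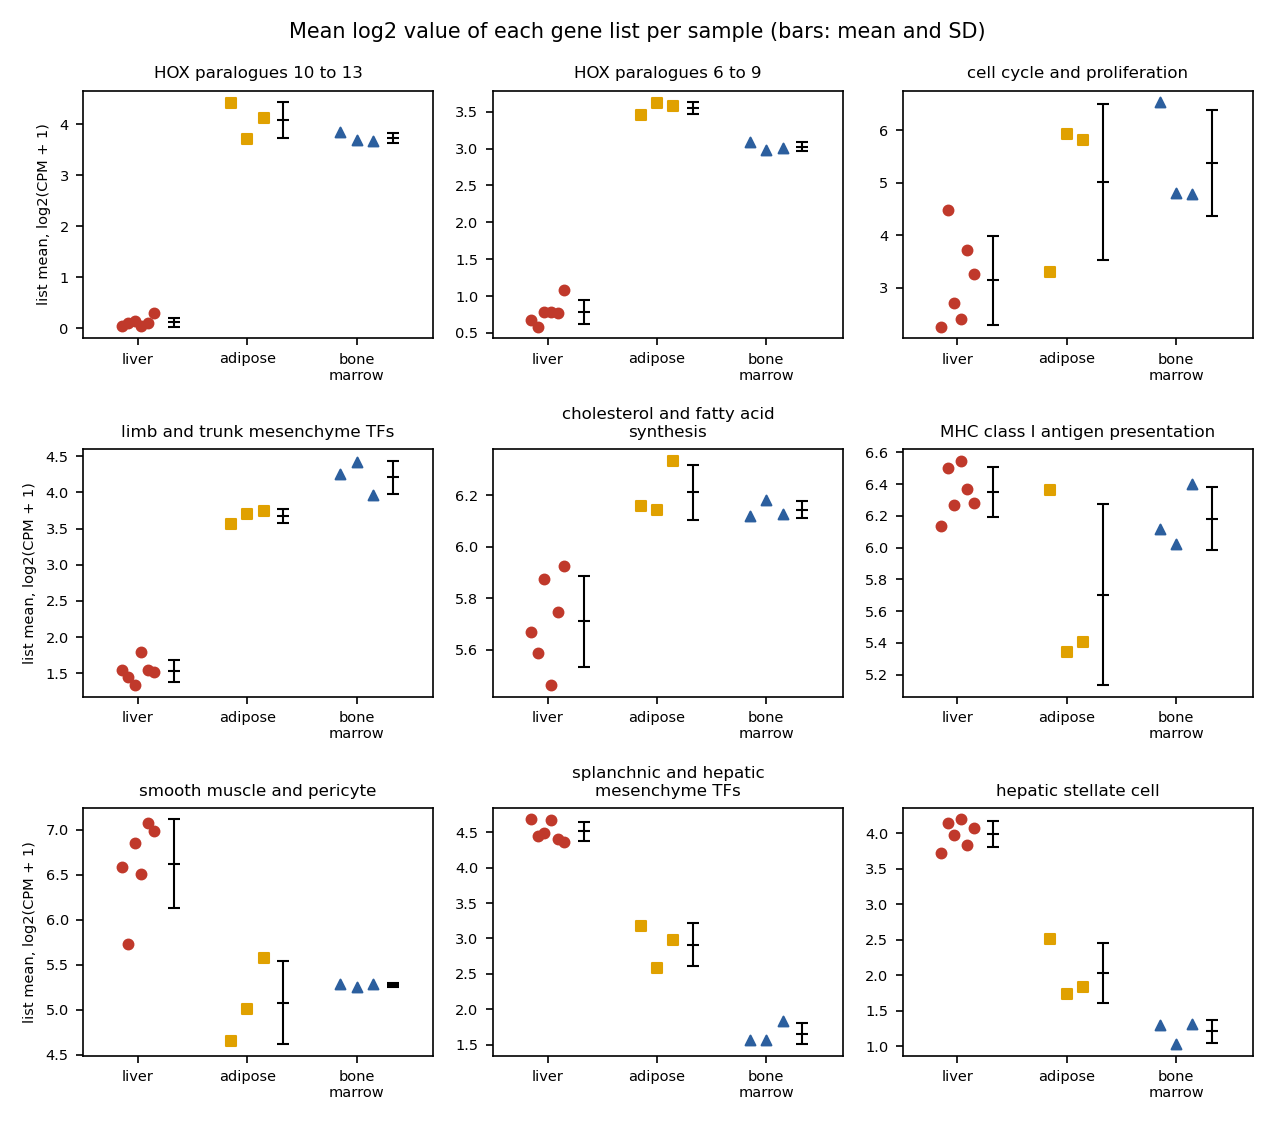
Mean log2(CPM + 1) of the members of the 9 called gene lists, 1 point per culture by tissue, with bars for the mean and SD. The liver cultures lie apart from all others in 7 panels and overlap with them in the cell cycle panel, where adipose 1 has a mean of 3.30, and in the MHC class I panel.

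Matrix and secreted factors changed in both directions, and none of their lists passed camera. Among 21 collagens 4 rose and 4 fell (5 and 4 adjusted over the list alone, limma camera adjusted p = 0.891; the median and mean were -0.12 while the test pointed up). COL4A1 rose from 330 ± 242 to 3383 ± 1203 CPM and COL4A2 from 276 ± 167 to 2766 ± 873 CPM (log2 differences of 3.68 and 3.51). COL15A1 (3.21) and COL18A1 (1.86) rose too, while COL14A1 (-3.75), COL8A2 (-2.62) and COL10A1 (-2.36) fell beside COL11A1. The major fibrillar chains COL1A1 (-0.21, adjusted p = 0.685) and COL3A1 (0.80, adjusted p = 0.255) did not pass in limma. Matrix glycoproteins gave 5 higher and 7 lower of 26 (6 and 8 adjusted over the list alone, limma camera adjusted p = 0.657, median -0.07), with NID2 (2.76), PRELP (2.15) and NID1 (1.29) higher and OGN (-2.02) lower. Proteases and cross-linkers gave 2 higher and 5 lower of 24 (3 and 8 adjusted over the list alone, limma camera adjusted p = 0.125, median -0.37). MMP11 (1.91) and PLAT (2.12) rose, and MMP3 (-2.60), MMP16 (-2.58), SERPINE2 (-1.46), LOXL1 (-1.38) and MMP14 (-0.55) fell.

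Signalling genes followed the same split. BMP2 (3.88), GREM1 (3.21), FST (2.68), TGFB2 (2.42), BAMBI (1.25) and LTBP4 rose among 22 genes of BMP and TGF-beta signalling. Among the 5 that fell were CHRDL1 (-2.98), LTBP2 (-1.20), LTBP3 (-0.86) and TGFB1 (-0.46; 6 and 6 adjusted over the list alone, limma camera adjusted p = 0.83; median -0.12, mean 0.33, test up). Of 12 WNT genes SFRP1 and DKK3 (2.65) rose, while DKK2 (-3.68) and WNT7B (-2.44) fell (2 and 3 adjusted over the list alone, limma camera adjusted p = 0.328, median -0.84). Of 23 growth factors 5 rose, HGF, IGF2 (2.90), PDGFA (2.14), PGF (1.98) and BDNF (1.35), and 4 fell, NRG1 (-3.97), GDNF (-1.75), IGF1 (-0.98) and KITLG (-0.87; 5 and 6 adjusted over the list alone, limma camera adjusted p = 0.638, median 0.20). Among 9 IGFBP and IGF2BP genes, IGFBP5, IGFBP7 (1.91), IGF2BP3 (1.37) and IGF2BP2 (0.46) rose, and IGFBP3 (-3.29) and IGFBP6 (-1.09) fell (5 and 2 adjusted over the list alone, limma camera adjusted p = 0.171, median 0.45). Retinoid genes gave 3 higher, among them RARRES2 (3.26) and RARRES3 (1.54), and 2 lower of 11, CRABP2 (-3.73) and ALDH1A3 (-3.09; 3 and 2 adjusted over the list alone, limma camera adjusted p = 0.83, median -0.11).

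Immune mediators included large single changes. Of 26 immunosuppressive genes 7 rose and 5 fell (9 and 5 adjusted over the list alone, limma camera adjusted p = 0.232, median 0.44). TGFB2, HGF and LGALS9 (1.70) rose, and PTGES (-1.97), HMOX1 (-1.47), NT5E (-1.42) and CD276 (-0.74) fell. VCAM1 (3.12, adjusted p = 0.0502), IL6 (0.68, adjusted p = 0.61) and PTGS2 (0.91, adjusted p = 0.46) did not pass in limma. Of 21 chemokine and cytokine genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, limma camera adjusted p = 0.166, median 0.65), among them the eosinophil chemokine CCL11 (3.87), TSLP (3.73) and IL1B (2.94), with IL11 lower (-1.25). Of 17 complement genes 4 rose, MASP1 (3.98), C7 (3.88), C4A (1.54, not separable from C4B) and C2 (1.52), and CFI (-1.67) and C5 (-0.67) fell (5 and 2 adjusted over the list alone, limma camera adjusted p = 0.275, median 0.30).

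Markers of other cell types were few in the table. None of 15 hepatocyte genes was in the table, and of the haematopoietic genes only LAPTM5 was, which did not pass (0.81). The macrophage gene CD68 fell by 0.92, of the endothelial genes EGFL7 rose (1.44) and TEK did not pass, and the mesothelial genes PRG4 and BNC1 did not pass. Of 4 epithelial genes KRT8 (254 ± 112 against 18.0 ± 13.9 CPM, log2 3.99) and KRT18 (633 ± 278 against 43.9 ± 37.7 CPM, log2 4.20), keratins also made by some stromal cells, rose. KRT19 fell by 1.42 and KRT7 did not pass (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.344, median 1.62). Among 9 surface markers used to define mesenchymal stromal cells, PDGFRB rose by 0.86 and NT5E fell by 1.42, while THY1 (-0.46), ENG (0.14) and CD44 (-0.24) did not pass (1 and 1 adjusted over the list alone, limma camera adjusted p = 0.799, median -0.06). Portal fibroblast genes gave 2 higher, GREM1 and COL15A1, and 1 lower of 9, DPT (-2.38; 3 and 2 adjusted over the list alone, limma camera adjusted p = 0.773, median -0.73). Of 4 adipocyte genes the fatty acid transporter CD36 (4.52) rose and FASN fell (1 and 1 adjusted over the list alone, limma camera adjusted p = 0.657, median 0.59). None of 4 osteoblast genes was called (limma camera adjusted p = 0.162, median -1.09; RUNX2 -0.40). Chondrocyte genes split into 3 higher of 9, SOX5 (2.94), ACAN (1.87) and SOX6 (1.38), and 5 lower, HAPLN1, COL11A1, COMP (-4.26), SOX9 (-2.46) and COL10A1 (3 and 5 adjusted over the list alone, limma camera adjusted p = 0.371, median -2.36).

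The remaining lists were not called by camera. Senescence genes gave 4 higher and 6 lower of 15 (6 and 6 adjusted over the list alone, limma camera adjusted p = 0.930; median -0.10, mean 0.02, test up), with CDKN1A (0.77) and SESN1 (0.43) higher and CDKN2B (-1.36) and TP53I3 (-1.06) lower. Glycolysis and hypoxia genes gave 3 higher, ALDOC (1.49), HK2 (1.29) and SLC2A3 (0.82), and 1 lower of 18, ENO1 (-0.45; 2 and 1 adjusted over the list alone, limma camera adjusted p = 0.0871, median 0.52). Immediate early genes gave ATF3 (1.44), BTG2 (1.42) and KLF2 (1.02) higher and EGR3 (-1.90) lower of 17 (3 and 1 adjusted over the list alone, limma camera adjusted p = 0.232, median 0.41). MT1F (1.04) was the called 1 of 7 metallothioneins and RPL15 (0.30) of 33 ribosomal protein genes, and neither was called adjusted over the list alone (limma camera adjusted p of 0.428 and 0.329, medians 0.48 and 0.05). In all 9 of 34 lists were called, 4 up and 5 down, of which 4 held with an estimated correlation; 47 of 100 splits of the 12 samples, the real one included, gave as many lists at the preset correlation and 1 of 100 with the estimated. The test fry called 12. It asks whether the genes of a list move one way, and unlike camera does not weigh them against the other genes. It added HOX groups 1 to 5, interferon-stimulated genes, WNT genes and the list of IGFBP and IGF2BP genes (limma fry adjusted p of 1.91e-06, 0.0155, 0.0259 and 0.00195). It did not call MHC class I (0.0533). Without adipose 1 the count was 13, and with the cell cycle mean as a covariate 7 of the 9 were still called.

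Of 165 called genes among those named for this comparison, 132 kept their call whichever sample was left out. The call ended in at least 1 such fit for 33, among them KRT19, COL15A1, SOX6, ACAN, COL10A1, HOXB3, COL8A2, DCN, MMP14, LOXL1, SERPINE2, PSME1, ERAP1, IFI44, IL15, IL11, C2, C4A, C5, CFI, IGF1, KITLG, IGF2BP2, CDKN1A, HK2, SLC2A3, ENO1, MT1F, RPL15 and LAMA3, with limma adjusted p up to 0.103 for KRT19 without liver 3. Under all 28 alternatives together 59 of the 165 kept their call.

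Against adipose alone, COL4A5, IGFBP5, GATA4, VCAM1 and EPHA3 were among the 6 named genes higher in liver, and MFAP5 and FBN2 among the 6 lower. COL4A5 averaged 258 ± 55.7 CPM in liver (n = 6) and 4.92 ± 2.78 CPM in adipose (n = 3). VCAM1, which binds leukocytes, averaged 275 ± 105 against 12 ± 17.6 CPM, and EPHA3, an ephrin receptor, 41.5 ± 23.3 against 0.195 ± 0.112 CPM. MFAP5, a microfibril protein, averaged 21.6 ± 32.8 CPM in liver and 542 ± 95.6 CPM in adipose. Every liver sample was apart from every adipose sample for each of the 12 genes named here, as the rule for naming them required. COL4A5 differed by 5.55 on the log2 scale (limma adjusted p = 1.60e-07), SLC7A2 by 5.43 (3.02e-05), IGFBP5 by 5.38 (3.68e-05), VCAM1 by 5.36 ± 0.76 (0.000674), GATA4 by 5.11 (2.19e-06) and EPHA3 by 5.01 (4.37e-05). MFAP5 differed by -5.49 (limma adjusted p = 0.000972), FBN2 by -5.45 (0.00193), MXRA5 by -5.42 (0.00162), TENM3 by -5.38 (1.01e-05), the cytoskeletal linker EPB41L3 by -5.17 (3.43e-05) and PTGFRN by -5.10 (0.00026). In limma 3072 genes were called, 1653 higher and 1419 lower in liver (768 and 506 with a difference of at least 1), and the samples did not overlap at 2956 genes (20.1%, against 2.38% by chance). The count was 1416 without adipose 2, 1512 without adipose 3, 1411 without the 2 deepest libraries and 1169 with the cell cycle mean as a covariate. It was 1447 with a replicate block and 6840 with sample quality weights.

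Against bone marrow alone, COL4A5, SFRP1, F3 and PTGS1 were among the 6 named genes higher in liver, and HAPLN1 and FLG among the 6 lower. SFRP1 averaged 220 ± 108 CPM in liver (n = 6) and 1.55 ± 0.448 CPM in bone marrow (n = 3). F3, the tissue factor that starts clotting, averaged 159 ± 54.5 against 1.68 ± 1.07 CPM, and PTGS1, a cyclooxygenase, 648 ± 200 against 11.5 ± 8.01 CPM. FLG, the filaggrin gene of the outer skin (ENSG00000143631, chromosome 1, 152274651 to 152297679), averaged 1.09 ± 0.814 CPM in liver and 245 ± 106 CPM in bone marrow. HAPLN1 averaged 1.5 ± 1.11 against 685 ± 340 CPM. No liver sample overlapped a bone marrow sample at the 12 genes named here, as the rule for naming them required. COL4A5 differed by 7.04 on the log2 scale (limma adjusted p = 1.80e-08), SFRP1 by 6.31 (8.18e-07), SLC7A2 by 6.08 (8.42e-06), F3 by 5.89 (1.23e-06), PTGS1 by 5.85 (1.03e-06) and CD36 by 5.84 (0.00034). HAPLN1 differed by -8.10 (limma adjusted p = 2.32e-05), FLG by -6.85 ± 0.36 (2.53e-07), COL11A1 by -6.35 (0.000341), NDNF by -6.07 (1.98e-07), FNDC1 by -6.04 (3.2e-05) and the cartilage protein COMP by -5.61 (0.00256). By limma 3375 genes were called, 1784 higher and 1591 lower in liver (909 and 758 with a difference of at least 1), with no overlap at 3878 genes (26.4%, against 2.38% by chance). The count was 1881 without bone marrow 1, 1789 without the 2 deepest libraries, and 1081 with the cell cycle mean as a covariate, where COMP was not called (limma adjusted p = 0.0945). It was 1976 with a replicate block and 5222 with sample quality weights.

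The calls against both tissues overlapped. Of the liver genes, 1610 were called in the same direction against adipose and against bone marrow, 932 higher and 678 lower. Independent lists of these sizes would share 354 genes. Because both comparisons use the same 6 liver samples, the liver samples were also split into 3 and 3, each group compared with 1 tissue. The median overlap over 20 splits was 861 genes (762 to 1028), and the overlap of independent lists of those sizes was not computed. Simulated data with no effect gave 0 in 20 simulations, a count fixed nearly in advance, since few genes can be called there. The log2 fold changes correlated at 0.722 over genes, against 0.333 in the simulations and a median of 0.667 with split livers; their covariance was 0.472 against 0.0205 and 0.450. Of the 3785 genes called against non-liver cells, 237 also differed between adipose and bone marrow.

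Between adipose and bone marrow cells, EPB41L3, FBLN2 and PTX3 were among the 6 named genes higher in adipose, and FLG and IGFBP2 among the 6 lower. EPB41L3 (ENSG00000082397, chromosome 18, 5392383 to 5630699) averaged 125 ± 42.3 CPM in adipose and 2.84 ± 3.29 CPM in bone marrow (n = 3 each). FBLN2, the matrix protein fibulin 2 (ENSG00000163520, chromosome 3, 13573824 to 13679922), averaged 338 ± 40.7 against 8.70 ± 4.50 CPM, and the innate immune pentraxin PTX3 1393 ± 817 against 56.4 ± 51.6 CPM. In the other direction FLG averaged 3.79 ± 1.37 CPM in adipose and 245 ± 106 CPM in bone marrow, and IGFBP2 0.589 ± 0.553 against 53.9 ± 31.4 CPM.

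By limma 863 genes were called, 429 higher and 434 lower in adipose (254 and 280 with a difference of at least 1). The groups did not overlap at 3788 genes (25.7%), where chance gives 10%. The genes named next were taken only from these, so their lack of overlap follows from the rule. EPB41L3 differed by 5.30 ± 0.55 on the log2 scale (limma adjusted p = 0.000371), FBLN2 by 5.26 ± 0.71 (0.0016), the glycosyltransferase GALNT12 by 5.19 ± 0.57 (0.000511), PTX3 by 4.78 ± 0.58 (0.000896), the neutrophil chemokine CXCL6 by 4.77 ± 1.07 (0.0228) and F3 by 4.46 ± 0.44 (0.000239), each with 3 of 3 adipose samples above all bone marrow samples. FLG differed by -5.60 ± 0.42 (limma adjusted p = 4.38e-05), HAPLN1 by -5.23 ± 0.88 (0.00523), IGFBP2 by -5.02 ± 0.89 (0.00681), CLSTN2 by -5.01 ± 0.67 (0.00148), KIAA1644 by -4.79 ± 0.51 (0.000388) and VCAM1 by -4.48 ± 0.87 (0.0116), in 3 of 3 samples. The count was 528 without adipose 2, 557 without adipose 3, 502 without bone marrow 2 and 477 without bone marrow 3. It was 513 with the samples of these tissues alone, 542 with a replicate block, 321 without the 2 deepest libraries, 1676 with DESeq2 and 3451 with sample quality weights. Calls also ended for HAPLN1 (adjusted p up to 0.06), IGFBP2 (0.0628), VCAM1 (0.0911; 0.0527 without bone marrow 3) and CXCL6 (0.0912; 0.0638 without bone marrow 1 and 0.0819 without bone marrow 2) under some settings of limma or edgeR.

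**Figure D4:**
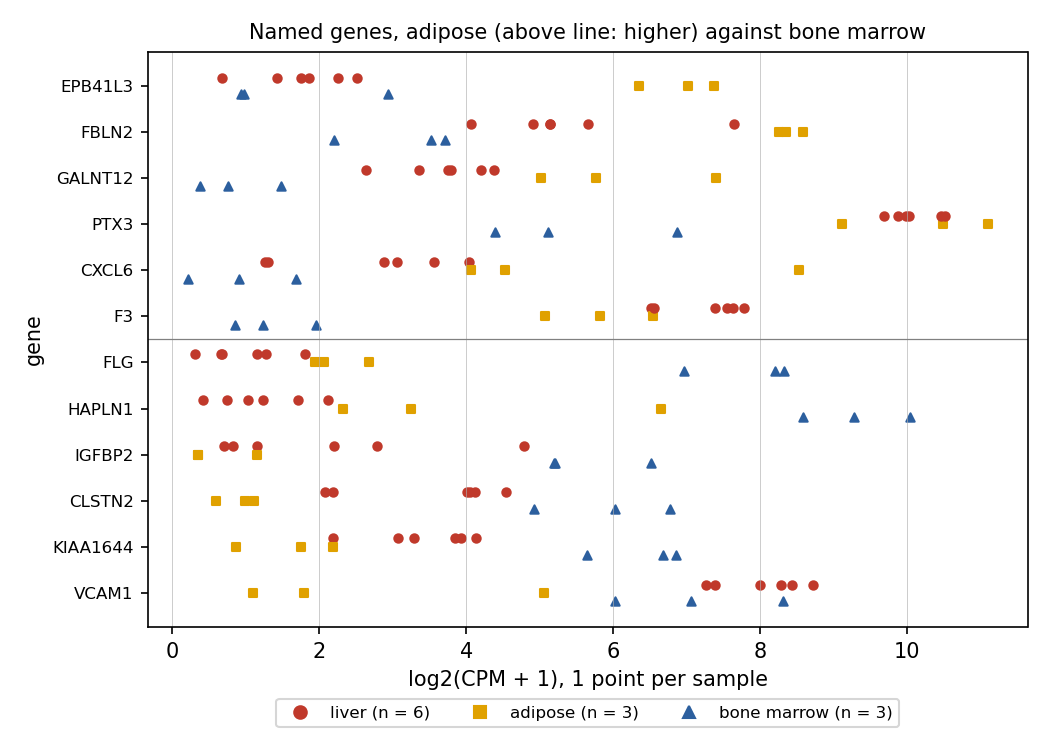
Values as log2(CPM + 1) on the horizontal axis for the 12 genes with the largest rise (above the line) and fall (below it) between adipose and bone marrow cultures, 1 point per culture, with the 6 liver cultures beside them. The 3 adipose and 3 bone marrow cultures do not overlap at any of the 12 genes, as the rule for naming them required.

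Chemokine genes led the lists that were higher in adipose. Of 21 chemokines and inflammatory cytokines 6 rose and none fell (13 adjusted over the list alone; median 2.32, 3 of 3 samples, limma camera adjusted p = 9.01e-06, adjusted p = 0.284 with an estimated correlation): the alarmin IL33 (4.08), CXCL5 (3.80), IL32 (2.60), CCL20 (2.32), CXCL2 and CXCL6. Adipose 1 had a list mean of 5.35, above adipose 2 and 3 at 3.57 and 3.29. Portal fibroblast genes rose at 4 of 9, FBLN2, GREM1 (3.5), PI16 (2.94) and DPT (1.94), with 6 adjusted over the list alone (median 2.41, 3 of 3 samples, limma camera adjusted p = 5.22e-05, adjusted p = 0.111 with an estimated correlation). Splanchnic factors rose at 4 of 10, HAND2 (3.76), FOXF1 (2.86), GATA6 (2.36) and HLX (1.08), with 5 adjusted over the list alone (median 0.82, 3 of 3 samples, limma camera adjusted p = 5.22e-05, adjusted p = 0.0624 with an estimated correlation). HOXC8 (1.81) and HOXC6 (1.26) rose among 9 HOX genes of groups 6 to 9 (2 adjusted over the list alone; median 0.34, 3 of 3 samples, limma camera adjusted p = 0.0119, adjusted p = 0.257 with an estimated correlation).

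The lists called lower in adipose were those of MHC class II, MHC class I, osteoblast and chondrocyte genes, none of them with an estimated correlation. Of 7 class II genes CD74 (-3.86), HLA-DRA (-2.84) and HLA-DMA (-1.36) fell in adipose (4 adjusted over the list alone; median -1.19, 3 of 3 samples, adipose 1 at a list mean of 2.06 against 1.41 and 1.38, limma camera adjusted p = 0.000241, adjusted p = 0.111 with an estimated correlation). Of 17 class I genes NLRC5 fell by 0.97 (1 adjusted over the list alone; median -0.36, 2 of 3 adipose samples below all bone marrow samples, adipose 1 at a list mean of 6.37 against 5.34 and 5.40, limma camera adjusted p = 0.0180, adjusted p = 0.532 with an estimated correlation). Among 4 osteoblast genes 2 fell, DLX5 (-2.48) among them, while RUNX2 was at -0.93 (limma adjusted p = 0.0549), with 3 adjusted over the list alone (median -1.18, 3 of 3 samples, limma camera adjusted p = 0.000448, adjusted p = 0.0624 with an estimated correlation). Of 9 chondrocyte genes HAPLN1 and COL10A1 (-2.90) fell (1 higher and 3 lower adjusted over the list alone; median -1.39, 3 of 3 samples, adipose 1 at a list mean of 2.15 against 3.26 and 3.32, limma camera adjusted p = 0.0268, adjusted p = 0.284 with an estimated correlation).

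A further 9 lists were called higher in adipose, each on few or no single genes. In 6 of them adipose 1 had the highest list mean of the 3 adipose samples: ribosomal (8.55, against 8.26 and 8.26 in adipose 2 and 3), metallothionein (4.53, 3.38 and 3.29), stellate (2.52, 1.74 and 1.84), complement (6.25, 4.68 and 5.16), retinoid (5.42, 3.97 and 4.66) and glycolysis (7.26, 5.95 and 5.69). Ribosomal protein genes had a median of 0.22 with 0 of 33 called (0 adjusted over the list alone; 3 of 3 samples, limma camera adjusted p = 4.60e-05, adjusted p = 0.532 with an estimated correlation). Of 4 epithelial genes KRT8 was at the threshold (1.99, limma adjusted p = 0.04998, 3 of 3 samples), and its call ended in 8 of the 12 fits with a sample left out. KRT18 was at 2.16 (limma adjusted p = 0.0605), with 3 called adjusted over the list alone (median 2.08, 3 of 3 samples, limma camera adjusted p = 0.00482, adjusted p = 0.257 with an estimated correlation). Immediate early genes (median 0.67) and metallothioneins (median 0.81) had 0 called of 17 and of 7, and 0 adjusted over the list alone (3 of 3 samples above the bone marrow mean; limma camera adjusted p of 0.0180 and 0.0251; adjusted p of 0.568 and 0.495 with an estimated correlation). Of 10 stellate genes 2 rose, HAND2 among them (3 adjusted over the list alone; median 0.22, 3 of 3 samples, limma camera adjusted p = 0.0278, adjusted p = 0.264 with an estimated correlation). PPARG, the adipocyte master regulator, rose by 2.01 among 4 adipocyte genes (2 adjusted over the list alone; median 1.20), and CD55 (1.87) and MASP1 (2.13) among 17 complement genes (2 adjusted over the list alone; median 0.50), each in 3 of 3 samples. Both lists had a limma camera adjusted p = 0.0444, and with an estimated correlation the adjusted p was 0.257 and 0.532. ALDH1A3 (2.45) and CRABP2 (1.68) rose and RARG (-1.0) fell among 11 retinoid genes (7 and 2 adjusted over the list alone; median 1.68, 3 of 3 samples). PFKP (1.08) and NDRG1 (1.19) rose among 18 glycolysis genes (3 adjusted over the list alone; median 0.44, 1 of 3 samples). The limma camera adjusted p was again 0.0444 for both lists, and with an estimated correlation the adjusted p was 0.532 and 0.685. Without adipose 1 the glycolysis list pointed the other way (limma camera adjusted p = 0.618).

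Lists that were not called still held called members. Of 15 limb and trunk factors EN1 (1.20) and TBX18 (1.62) rose and MEOX2 (-2.99), SIX2 (-2.97) and TWIST1 (-0.91) fell (3 and 7 adjusted over the list alone, limma camera adjusted p = 0.0588, median -0.40). HOXA11 (1.51) was the called 1 of 3 HOX genes of groups 10 to 13 (1 adjusted over the list alone, limma camera adjusted p = 0.705; median -0.22, mean 0.36, test up), and none of 9 in groups 1 to 5 was called (limma camera adjusted p = 0.553, median 0.12). Of 21 collagens COL3A1 (2.03), COL18A1 (1.81), COL5A1, COL5A3 and COL16A1 rose and COL8A2 (-3.82) and COL10A1 fell (8 and 3 adjusted over the list alone, limma camera adjusted p = 0.0543, median 0.50). Of 26 matrix glycoproteins FBLN2 and FBLN5 (1.55) rose and OGN (-1.63) and OMD (-1.62) fell (7 and 2 adjusted over the list alone, limma camera adjusted p = 0.0713, median 0.45). Of 24 proteases and cross-linkers MMP3 (2.18), TIMP4 (2.45), LOX, LOXL2 and LOXL3 rose and ADAMTS5 (-3.77), MMP13 (-2.75) and LOXL1 fell (5 and 3 adjusted over the list alone, limma camera adjusted p = 0.553, median 0.01).

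Of 26 immunosuppressive genes PTGS2 (3.29), TNFAIP6 (3.09) and CD55 rose and VCAM1 fell (4 and 1 adjusted over the list alone, limma camera adjusted p = 0.256, median 0.14). Of 28 interferon-stimulated genes IFI27 (3.57) rose and OAS2 (-2.19) fell (2 and 2 adjusted over the list alone, limma camera adjusted p = 0.294, median -0.16). WNT2 (3.75) and SFRP1 (3.23) rose and WNT5B (-3.01) and WNT9A (-1.89) fell of 12 WNT genes (3 and 3 adjusted over the list alone, limma camera adjusted p = 0.471, median 0.26). BMP6 (2.51) and GREM1 rose and CHRDL1 (-3.77), BMP4 (-2.98) and GDF5 (-2.88) fell of 22 BMP and TGF-beta genes (2 and 4 adjusted over the list alone, limma camera adjusted p = 0.105, median -0.24). Of 23 growth factors 1 rose and PDGFC (-1.19) fell (1 and 1 adjusted over the list alone, limma camera adjusted p = 0.294, median -0.32). Of 9 IGFBP and IGF2BP genes IGFBP2 fell (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.659, median -0.05, mean -0.35, test up). Smooth muscle genes gave ABCC9 (2.52) higher and CSPG4 (-1.62) lower of 13 (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.471, median -0.33). Of 20 lipid synthesis genes SREBF1 (0.61) rose (1 adjusted over the list alone, limma camera adjusted p = 0.614, median 0.08). None of 9 stromal surface markers, 28 cell cycle genes or 15 senescence genes was called, also adjusted over the list alone (limma camera adjusted p of 0.471, 0.294 and 0.183; medians of -0.34, -0.34 and 0.20). The measured members of the haematopoietic, macrophage, endothelial and mesothelial lists did not pass, with 1 mesothelial gene higher adjusted over the list alone.

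In all 17 of 34 lists were called between adipose and bone marrow, 13 up and 4 down, and none with an estimated correlation. The test fry called 11, adding limb and trunk factors and not calling the ribosomal, immediate early, metallothionein, complement, retinoid, glycolysis and MHC class I lists (limma fry adjusted p up to 0.412). The count of lists was 10 without bone marrow 2 and 11 without adipose 1. Leaving out a single sample ended the call of the stellate, chondrocyte, adipocyte, complement, retinoid, glycolysis, metallothionein, MHC class I and immediate early lists, with a limma camera adjusted p up to 0.618 for glycolysis without adipose 1. Of 83 called genes named for this comparison, 48 kept their call whichever sample was left out. It ended in at least 1 such fit for 35, among them KRT8, CXCL6, VCAM1, DPT, CSPG4, PPARG, GATA6, TBX18, TWIST1, COL3A1, COL5A1, COL5A3, COL16A1, OGN, OMD, LOX, LOXL3, LOXL1, PTGS2, NLRC5, HLA-DMA, IFI27, OAS2, MASP1, WNT2, WNT5B, WNT9A, BMP6, PDGFC, ALDH1A3, CRABP2, RARG, NDRG1 and SREBF1, with limma adjusted p up to 0.161 for KRT8 without bone marrow 2. Under all 27 alternatives together 31 of the 83 kept their call.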

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

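The tests of the 3 patterns weighed here, and the splits for lists with an estimated correlation, were chosen only after the result was seen; the other splits of the samples were planned before. For the position of adipose 1 and for depth, the test was also given a new form after its first result, and both values are given. The test of shared HOX reads replaced an earlier one, a count of limb and trunk factors called lower (13 of 15), which could not show whether HOX reads were shared.

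Adipose 1 lay between liver and the other non-liver samples, at 59.2 on an axis from the mean of liver (0) to the mean of the other 5 non-liver samples (100), where the lowest of those 5 stood at 92.8 and the highest liver sample at 9.78. Admixture of liver-derived cells is argued against, since adipose 1 lay a median of 35.6% of the way to liver over 1389 genes (quartiles 1.55% and 95.3%), yet 6 genes that only liver expressed stood at a median of 0.374% of their liver level (quartiles 0.108% and 0.678%, highest 2.62%). Lower expression of cell cycle genes in adipose 1 may account for part of the distance. With the slope within tissues removed from all samples adipose 1 stood at 68.2 and the lowest of the other 5 at 90.3. In the second form, at the cell cycle mean of adipose 2 and 3, adipose 1 stood at 80.1 (95% bounds 70.5 and 89.6), below 92.8. Whether cell cycle expression accounts for the whole distance cannot be told from these values. The bounds carry only the error of the slope, and the 5 samples that set 92.8 also helped choose the axis genes. For scale, liver 6 moved from 9.78 to 17.3 when it was left out of that choice. A wrong label on a liver or a bone marrow culture is argued against: adipose 1, at 59.2, lay above the 95% bound of 33.9 for a further liver sample, and on an axis from bone marrow (0) to adipose 2 and 3 (100) it lay at 84.0, above the bound of 41.6 for a further bone marrow sample (samples left out in turn reached 17.3 and 16). Beyond the expression of cell cycle genes no biological explanation was tested, such as differences between people or fat depots, because the design gives no group that sets adipose 1 apart, and a culture from another source was not tested either.

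All 28 cell cycle genes were lower in liver, with a list mean of 3.14 ± 0.86 against 5.20 ± 1.16 (log2, SD, n = 6 each), liver from 2.26 to 4.48 and non-liver from 3.30 to 6.55. The authors' scaling is argued against, because the median stayed at -2.08 with size factors computed on the values. A difference in depth between libraries as the whole cause is argued against too: without the 2 deepest libraries the median was -1.49 in the first form of the test, with 28 of 28 genes below 0 though only 4 called, and in the second form the list mean differed by -1.54 (exact two-sided permutation p = 0.0429, 210 splits). Culture stage at harvest apart from tissue cannot be told apart from a difference between tissues in proliferation: the list mean differed (exact two-sided permutation p = 0.0108, 924 splits), but passage and confluency at harvest are not given per sample in the sources used here. Both stay open, and the tissue itself was tested only through the groups.

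Of the measured HOX genes of groups 6 to 13 and the limb and trunk factors, 24 were lower in liver. A difference in expression of cell cycle genes is argued against as the whole cause. With the cell cycle mean as a covariate all 24 stayed below 0, with a median of -2.74 before and -2.79 after. Of the 24, 18 (75%) were still called lower, against 15.6% of all called genes. These shares are not alike: all called genes had a median absolute difference of 0.744, and the covariate raised the median SE from 0.138 to 0.194. Reads shared between overlapping HOX coding genes are argued against only for the 7 HOX members that overlap no other such gene in the table, of which 7 were called lower (median -2.90, highest -1.06). For the 5 that overlap another, of which 4 were called lower, such reads cannot be told apart from a true difference, since the counts are given per gene, and overlap with antisense transcripts was not tested. A hypothesis left open, untested beyond the groups themselves, is that cultured stromal cells keep the positional code of the tissue they came from; it was found on the same data, and 18 calls under the covariate do not settle it.

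Across the splits of the samples, chance can be excluded for the counts of genes called between liver and the others. For liver against non-liver 1 of 100 splits, the real one with 3785 genes, gave as many, and the highest other gave 1128; for liver against adipose it was 1 of 84 with 3072 against 873, and for liver against bone marrow 1 of 84 with 3375 against 22. For adipose against bone marrow the 10 splits are too few for a share under 0.05, with 863 genes in the real split and 235 in the highest other. For gene lists between liver and non-liver, chance cannot be excluded at the preset correlation, where 47 of 100 splits gave at least the 9 lists called and the highest other gave 14. With an estimated correlation 1 of 100 splits, the real one, gave 4 lists and the highest other 0. These splits were chosen after the result was seen, so they do not exclude chance for the lists. Between adipose and bone marrow 2 of 10 splits gave as many lists as the 17 called, with 21 in the highest other, and 10 splits are too few for a share under 0.05.

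A single liver sample stood apart from the other 5 at 24 of 290 values tested, where chance alone gives about 14.5 at 1 in 20. The number given is the gap to the nearest sample as a share of the range of the 6 liver samples. Liver 6 was high among liver samples at HOXC6 (0.739), HOXA11 (0.725), HOXC10 (0.704), the mean of HOX groups 10 to 13 (0.645), COMP (0.797), GDNF (0.647), IGF2BP3 (0.647) and SOX9 (0.630). Its HOX values were low all the same. In log2(CPM + 1) HOXA11 was 0.168, HOXC10 0.148 and the mean of groups 10 to 13 0.294, where the lowest non-liver sample had a mean of 3.66. Liver 4 was high at SIX2 (0.877), LAMA5 (0.867), COL15A1 (0.762) and FBN2 (0.722). Liver 2 was low at ACTG2 (0.774), KLF2 (0.704), COL8A2 (0.697), MYL9 (0.637) and the mean of the epithelial list (0.733). Liver 1 was low at ACACA (0.671) and high at CFI (0.658), EN1 (0.680), HAS1 (0.670) and HLA-DMA (0.645). Liver 3 was high at HLA-DRA (0.669), though its value was only 0.198 in log2(CPM + 1), and liver 5 at SREBF1 (0.643). Groups of 3 were not tested in this way.

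Of the 24 genes named for liver against non-liver, 5 also differed between adipose and bone marrow, so that liver differed by another amount from each. By limma COL4A5 was higher in adipose by 1.49 (adjusted p = 0.0151), PDE10A by 0.90 (0.0349) and SFRP1 by 3.23 (0.00172), in 3 of 3 samples. HAPLN1 differed by -5.23 (limma adjusted p = 0.00523) and NDNF by -3.29 (0.000481), also in 3 of 3 samples.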

How the results depend on the processing

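The fits without the 2 deepest libraries (adipose 2 and bone marrow 1) and with the cell cycle mean as a covariate were chosen only after the data were seen; all other alternatives were planned. Main counts were 3785, 3072, 3375 and 863 genes (liver against non-liver, adipose and bone marrow, then adipose against bone marrow). A replicate block gave 1191, 1447, 1976 and 542 in the same order. Under this block liver 4, 5 and 6, alone in their replicate numbers, added nothing to the comparisons. Any further cause was not tested. HAPLN1 and NDNF lost their liver against non-liver call under the block, NDNF at a limma adjusted p of 0.0541. A minimum log2 fold change of 1 gave 1437, 1274, 1667 and 534, fewer by construction. Without the 2 deepest libraries the counts were 1949, 1411, 1789 and 321, with fewer samples; with the covariate they were 618, 1169 and 1081 for liver, where the cause was not tested beyond the larger SE (median 0.194 against 0.138). Sample quality weights gave 6840, 5222 and 3451 for the comparisons between tissues, and DESeq2 1676 and the samples of these tissues alone 513 for adipose against bone marrow; the cause was not tested. With each sample left out, counts ran from 2843 (without liver 4) to 4687 (without adipose 1) for non-liver; from 1416 (without adipose 2; 1512 without adipose 3) to 4435 (without adipose 1) for adipose; from 1881 (without bone marrow 1) to 4054 (without adipose 1) for bone marrow; and from 477 (without bone marrow 3; 502 without bone marrow 2, 528 without adipose 2, 557 without adipose 3) to 1075 (without liver 6) for adipose against bone marrow. Pseudocounts, filters, size factors, quantile normalization, robust moderation and edgeR kept each count within 1.5 times, as did the 3-tissue model and the exact rank-sum test for liver against non-liver. The overlap of calls against both tissues, 1610 genes, was 861 with split livers, which leaves 3 liver samples per comparison. Lists called between liver and non-liver numbered 9, and 4 with an estimated correlation, 12 with fry, with 9 to 13 (without adipose 1) when samples were left out. Between adipose and bone marrow they numbered 17, and 0 with an estimated correlation, 11 with fry, 11 with the covariate and 10 (without bone marrow 2) to 19 (without liver 1) when samples were left out, 11 without adipose 1; the cause was not tested. Direction turned for the cell cycle list with its own mean as covariate (adjusted p = 0.904 in limma, by construction), for the ribosomal list with that covariate (0.00137; the cause was not tested) and for the glycolysis list of adipose against bone marrow without adipose 1 (0.618; left-out range 0.000609 to 0.618). No named gene turned: of 5003 gene and setting pairs for liver against non-liver 4475 kept their side of the threshold, 518 lost and 10 gained a call, and 478 of 486, 461 of 486 and 2045 of 2394 kept it in the other comparisons. Of the lists, 657 of 680 pairs kept theirs for liver against non-liver and 597 of 680 for adipose against bone marrow. Samples sharing a replicate number were not paired: over 9 such pairs the correlation of their deviations from the tissue means ran from -0.29 to 0.31, with 2 above 0.1. Depth limited little, since 3 reads are at most 0.0511 CPM; the 2 deepest libraries were both non-liver.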

Other observations

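Only the test of the basement membrane genes was planned before its result was seen; the genes to describe were chosen after their values were seen.

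Liver cells took a middle place between adipose and bone marrow cells at a small set of genes. By limma 20 genes were called higher in liver than in adipose and lower than in bone marrow, and 19 the other way round. FBLN2, the fibulin of elastic matrix, averaged 338 CPM in adipose, 60.2 ± 68.7 CPM in liver and 8.70 CPM in bone marrow, with log2 differences of liver of -2.98 from adipose (limma adjusted p = 0.00629) and 2.28 from bone marrow (0.0204). GALNT12, an enzyme that starts O-glycosylation, differed by -2.38 (limma adjusted p = 0.00661) and 2.81 (0.00190). TM4SF1, a surface protein of endothelial and stromal cells, ran the other way, with 8.80 ± 7.19 CPM in adipose, 42.0 ± 14.8 CPM in liver and 113 ± 24.7 CPM in bone marrow (2.39, limma adjusted p = 0.00388, and -1.46, adjusted p = 0.0379). The arterial ephrin EFNB2 stood at 1.93 ± 1.68, 11.2 ± 2.88 and 31.4 ± 2.80 CPM in the same order (2.23, limma adjusted p = 0.00136, and -1.44, adjusted p = 0.0128). CLSTN2 (2.60 and -2.41) and KIAA1644 (1.81 and -2.98) followed it. Some of these calls ended when a sample was left out, in limma FBLN2 (adjusted p = 0.0935 without bone marrow 2), CLSTN2 (0.0736 without bone marrow 1), TM4SF1 (0.128 without bone marrow 3) and EFNB2 (0.0505 without bone marrow 1) against bone marrow and KIAA1644 (0.0886 without adipose 2) against adipose.

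COL4A5 and COL4A6 were among the 12 named genes with the largest rise in liver. Of 10 basement membrane genes already seen, 8 were higher (camera p = 4.92e-07, limma, and 0.0152 with an estimated correlation), a set picked because of its values. The hypothesis that basement membrane genes as a group may be higher in liver was put to the other members, and these did not pass (median log2 difference 0.12; camera p = 0.142, limma; 0.274 with an estimated correlation). Of 14 tested members, 5 were higher: the laminin chain LAMA5 (3.81), the netrin NTN4 (3.18), TINAGL1 (3.01), AGRN (1.03) and PXDN (0.96). Lower members numbered 2, among them the laminin chain LAMA3 (-2.29). The rise of COL4A1, COL4A2, COL4A5, COL4A6, NID1 and NID2 thus did not extend to the group as tested.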
